A study of Mus musculus with 6 samples.

How the data were processed

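Skin RNA from 6 mouse samples was measured by RNA sequencing, 3 from ATR WT mice and 3 from ATR mD/mD mice. Per the labels' protocols, tissue was homogenised with ceramic beads, and messenger RNA was selected with oligo dT beads from total RNA. Libraries were made with the TruSeq RNA v2 kit, a kit that does not mark the strand. Per the submitters' processing notes, the tools were FastQC, TopHat2 2.0.12 and edgeR, and the genome build was mm10. The read counter, the gene annotation and the filter on low counts are not given in the sources used here. The authors deposited 1 table of whole-number read counts per gene and library, with no normalization, and each library had its own column, per the file headers. The same deposited table holds a log2 fold change, an average log2 CPM, a p-value and an adjusted p-value per gene from the authors' own comparison, per the file headers.

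The table lists 14486 rows, of which 2 name no gene (reads aligned to more than 1 place and ambiguous reads). These 2 rows held between 4.93% and 5.73% of the listed counts of a library, and they were left out of library sizes and tests. The other 14484 genes carried between 34723600 and 46847751 counts per library. The lowest total of a gene over the 6 libraries was 171. The filter of edgeR's filterByExpr and a minimum of 1 CPM in at least 3 samples both left all 14484 genes, so neither filter changed anything. No 2 libraries of a group held the same counts: the chi-square statistic of their counts per degree of freedom, which is near 1 for sampling noise, lay at 55.5 or above in every pair within a group.

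Groups were taken from the sample labels. Counts were scaled with TMM (factors 0.923 to 1.04) and tested with edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3), with no covariate, and p-values were adjusted by the Benjamini-Hochberg method over 14484 genes. Fold changes are log2 values of ATR mD/mD against ATR WT, each with its standard error (SE), and CPM values are TMM-scaled means with their SD over 3 libraries. The SE of a gene was derived from the test, as the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic. It is therefore only a rough measure for genes with almost no counts in 1 group. For genes with very few counts in 1 group, the ratio of summed counts, scaled by library size, is given with its exact 95% counting interval. Such intervals cover counting error only and leave out the spread between libraries. They may be too narrow even for counting error, since PCR copies are not independent molecules. Positions come from the GENCODE M21 annotation of the same build, in which 13986 symbols of the table matched directly, 421 matched through an older symbol, and 14385 had 1 position. Reads of a gene and of an overlapping or antisense gene cannot be told apart in these counts, and counts of near-identical family members are uncertain.

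Before the data were examined, 32 gene lists were fixed, the test design was fixed, and the rule for naming genes was fixed. Of these lists, 31 had members in the table. The list of mitochondrially encoded genes had none and was not tested. Each list was tested with camera (limma 3.58.1) on log2 CPM with a preset inter-gene correlation of 0.01, and p-values were adjusted over the 31 lists. The same lists were tested with an estimated correlation and with fry. Members were also counted at an adjusted p under 0.05 over all genes and adjusted over the list alone. List medians in the report are medians of the members' edgeR log2 fold changes, whereas camera and the list values in the section on processing use differences of mean log2 CPM. The naming rule took Atr and Braf, then up to 12 genes in each direction with the largest change. These had to have an adjusted p under 0.05, a mean of at least 1 on the log2 CPM scale and no overlap between groups. Symbols of the Gm or Rik kind and sex-linked genes were passed over. It then took the 4 members with the smallest p of each list past the test and at most 2 of each other list. Some of the genes this rule took are not reported here. Rnaset2b, Alpi, Cfap74, the other Skint genes beside Skint3, Skint4 and Skint9, Trim34a, Trim30d, Trim12c, Trim30a, Jun, Zfp36, Dusp1, Ier2, Cd3d, Cd3e, Cd3g, Cd247 and, in the closing observations, genes near Atr and genes that jumped in single libraries lie outside this rule and were chosen after their values were seen.

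The comparison was repeated with DESeq2 size factors (RLE) in edgeR, no filter, a filter at 1 CPM, DESeq2 1.42.0, limma-voom, the replicate number as a block, stricter thresholds, and leaving out each library in turn. Alternatives chosen after the data were examined were covariates for the hair list level and for the level of 4 Y-linked genes, edgeR's exact test, robust quasi-likelihood estimation, a minimum of 10 CPM in at least 3 samples, and keeping the 2 rows without a gene. Each covariate together with an estimated correlation in camera, and a count of loci without keratin genes, were added in the same way. A change of pseudocount applied only to normalized values and was not run. The test was tried on simulated data with the real means and library sizes, for ATR mD/mD against ATR WT over 14484 genes with 200 genes changed. It recovered 11% of 2-fold changes and 69% of 4-fold changes, called 7 of 14284 unchanged genes and gave no wrong sign. A simulated list shifted by 0.5 on the log2 scale was called, and 0 of 30 unshifted lists were. Genes were drawn independently in this simulation, so it could not show how often camera calls unshifted lists whose members are correlated. In the real data, estimated correlations reached 0.96 (skeletal muscle genes).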

Results

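Skin of mice carrying a Braf CA allele and Cre was compared between animals with wild-type Atr (ATR WT) and animals in which part of the Atr kinase domain was removed (ATR mD/mD). Atr encodes a kinase that responds to stalled DNA replication, and Braf encodes a kinase of the MAPK pathway. Each group had 3 libraries. The labels give skin as the tissue and a C57BL/6-129J background, and the series design calls the samples nevi, which are benign growths of pigment cells. The labels do not say whether the samples of a group came from separate animals, so the p-values measure the spread between these samples. Gene counts summed to 39297160, 42185287 and 46847751 in ATR WT 1, 2 and 3, and to 34723600, 38565590 and 35642215 in ATR mD/mD 1, 2 and 3.

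The libraries differed most in hair follicle genes, and this difference did not follow genotype. The mean level of the 34 hair follicle and hair shaft genes was 7.09 log2 CPM in ATR WT 2, 7.25 in ATR WT 3 and 7.30 in ATR mD/mD 3. It was 2.01 in ATR WT 1, -0.10 in ATR mD/mD 1 and 2.31 in ATR mD/mD 2. The first principal component, with 70.4% of the variance of log2 CPM, separated the same libraries. Sex-linked transcripts were also uneven. Xist, the transcript of the inactive X chromosome, had 23005, 29207 and 18050 counts in ATR WT 2, ATR WT 3 and ATR mD/mD 1. It had 37, 40 and 23 counts in ATR WT 1, ATR mD/mD 2 and ATR mD/mD 3, the libraries in which the mean of 4 Y-linked genes was 4.75, 5.17 and 5.17 log2 CPM.

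**Figure D1:**
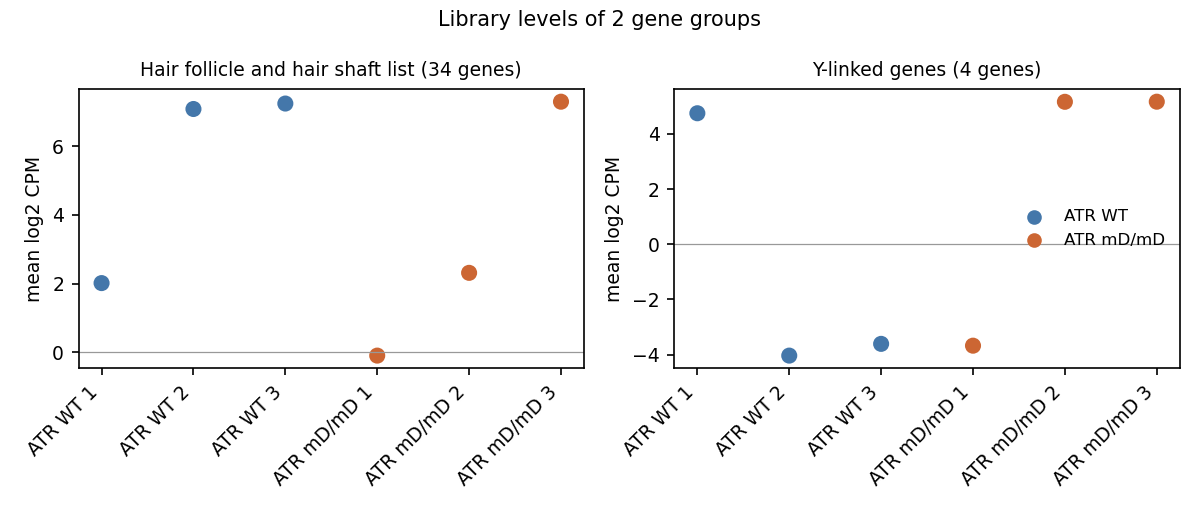
Mean log2 CPM of the 34 hair follicle and hair shaft genes (left) and of the 4 Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty (right), 1 point per library, with ATR WT in blue and ATR mD/mD in orange. Hair genes lay at 7.09 or above in 3 libraries and at 2.31 or below in 3, and neither measure divided the libraries by genotype.

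Atr itself (chromosome 9, 95857597 to 95951781, plus strand, mm10) had the same total expression in both groups within the replicate spread. Its level was 22.1 ± 3.87 CPM in ATR WT and 22.6 ± 2.00 CPM in ATR mD/mD (SD, n = 3), with 640, 1065 and 1182 counts against 728, 874 and 865. The log2 fold change was 0.03 (SE 0.172, adjusted p = 0.9999, edgeR quasi-likelihood), and it turned to -0.095 without ATR WT 1 and to -0.040 without ATR mD/mD 3. A count over the whole gene includes the exons outside the deleted part, so it does not check the deletion. Braf (chromosome 6, 39603237 to 39725463, minus strand) was at 32.3 ± 10.7 and 29.1 ± 7.60 CPM (SD, n = 3), a log2 fold change of -0.15 (SE 0.304, adjusted p = 0.9999, edgeR). Its sign turned without ATR WT 3 (0.060) and without ATR mD/mD 1 (0.0026).

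Of 14484 genes, 7 fell in ATR mD/mD skin and 0 rose at an adjusted p under 0.05 (edgeR quasi-likelihood). In 6 of the 7, the transcript was close to absent from all 3 ATR mD/mD libraries. Skint3, Skint4 and Skint9 belong to a family of epidermal and thymic membrane proteins, whose founding member Skint1 is needed for a T cell population of the epidermis. Skint3 had 1511, 1264 and 1952 counts in ATR WT and 2, 1 and 1 in ATR mD/mD, a 1004-fold ratio (95% counting interval 392 to 3687, adjusted p = 0.000514, edgeR). Skint9 had 1663, 1135 and 1158 counts against 1, 0 and 0, a ratio of 3362 (603 to 132800, adjusted p = 0.0041, edgeR). Skint4 had 616, 582 and 948 counts against 1, 0 and 0, a ratio of 1824 (327 to 72070, adjusted p = 0.0041, edgeR). These 3 genes lie side by side on chromosome 4, from 112072016 to 112433985. Farther along the same cluster, Skint6 and Skint5 had log2 fold changes of -2.70 (SE 0.476, adjusted p = 0.645) and -2.36 (SE 0.446, adjusted p = 0.813, edgeR quasi-likelihood), not past the threshold. DESeq2 and edgeR's exact test called both, and Skint5 passed with the hair covariate (adjusted p = 0.0461, edgeR quasi-likelihood). The other measured members lay on both sides of 0, none past the threshold. Skint1, Skint2, Skint8 and Skint10 had log2 fold changes of 0.08 (SE 0.184), 0.04 (SE 0.187), 0.70 (SE 0.245, unadjusted p = 0.0264) and 0.63 (SE 0.469), and Skint7 and Skint11 had -0.39 (SE 0.292) and -0.99 (SE 0.594).

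Trim12a, a tripartite motif gene (chromosome 7, 104299894 to 104315466), had 373, 393 and 414 counts in ATR WT and 1, 0 and 0 in ATR mD/mD, a ratio of 1003 (180 to 39640, adjusted p = 0.00629, edgeR). Its neighbours Trim34a and Trim30d, within the same stretch, had log2 fold changes of -2.12 (SE 0.229, adjusted p = 0.0788) and -3.06 (SE 0.412, adjusted p = 0.212, edgeR quasi-likelihood). DESeq2 and edgeR's exact test called both of these neighbours. Trim12c and Trim30a did not follow, with 0.21 (SE 0.119) and -0.25 (SE 0.205). Ecel1 encodes a membrane metalloprotease related to endothelin-converting enzymes (chromosome 1, 87147655 to 87156521). It was at 36.3 ± 11.8 CPM in ATR WT and 0.422 ± 0.0871 CPM in ATR mD/mD (SD, n = 3), 85.5-fold lower (log2 fold change -6.42, SE 0.344, adjusted p = 0.0041, edgeR). The adjoining Alpi, an alkaline phosphatase gene, had 95, 825 and 524 counts against 1, 1 and 2, a ratio of 307 (120 to 1127), with an adjusted p of 0.134 (edgeR). With 1 library left out, its adjusted p ran from 0.0133 (without ATR WT 1, the only passing value) to 0.912 (without ATR mD/mD 2). Rnaset2b, a secreted-type ribonuclease gene (chromosome 17, 6970634 to 7011299), had 117, 203 and 134 counts against 2, 2 and 3 (log2 fold change -5.72, SE 0.415, adjusted p = 0.0109, edgeR). Zfp949, a zinc finger gene on chromosome 9 (88548020 to 88571061), 7.31 Mb from Atr, fell from 73.6 ± 8.17 to 22.9 ± 1.90 CPM (SD, n = 3), a log2 fold change of -1.69 (SE 0.137, adjusted p = 0.019, edgeR).

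**Figure D2:**
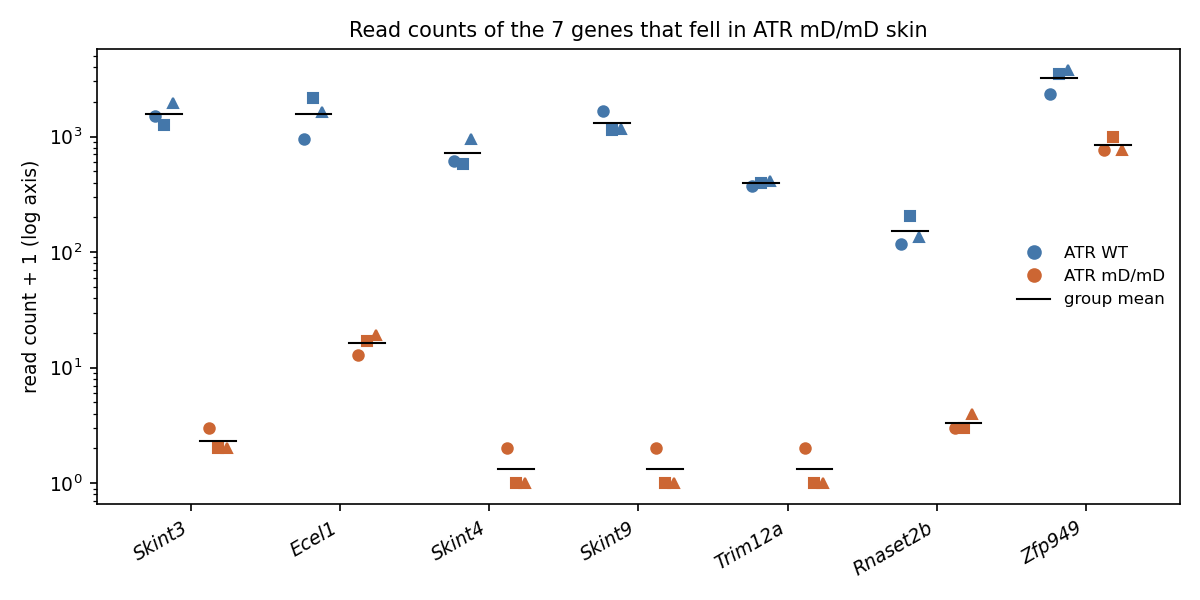
Read counts plus 1 on a log axis for the 7 genes that fell in ATR mD/mD skin, 1 point per library (circle, square and triangle for replicates 1, 2 and 3), with ATR WT in blue, ATR mD/mD in orange and a line at each group mean. Skint4, Skint9 and Trim12a had 1, 0 and 0 reads in the ATR mD/mD libraries, and Zfp949 kept 760 to 987 reads.

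At an unadjusted p under 0.05, edgeR gave 240 genes, of which 158 were lower and 82 higher in ATR mD/mD. The groups did not overlap in 701 genes, which is 4.84% of genes against the 10% that chance gives with 3 against 3. DESeq2 called 39 genes, 33 lower and 6 higher, limma-voom called 7 lower and 0 higher, and edgeR's exact test called 20 lower and 2 higher. The authors' deposited table holds 22 genes at an adjusted p under 0.05, 20 lower and 2 higher, and all 7 genes named above are among them. An edgeR exact test on all listed rows gave the same 22 genes, so the deposited calls and the exact test are not separate support. Skint3, Skint4 and Ecel1 kept their calls with any 1 library left out. Rnaset2b and Zfp949 kept theirs only without ATR WT 1. Their adjusted p was up to 0.128 (without ATR mD/mD 2) and up to 0.195 (without ATR mD/mD 1, edgeR). Trim12a lost its call without ATR WT 2 (0.0613) or ATR WT 3 (0.0530), and Skint9 without ATR mD/mD 1 (0.0819, edgeR). The number of calls was 4 without ATR WT 2, without ATR WT 3 or without ATR mD/mD 1. Skint, Trim and Rnaset2 genes have close relatives in the genome, so reads shared among copies make their exact counts uncertain.

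Immediate early genes, the first genes transcribed after a stimulus, fell as a group in ATR mD/mD skin. All 16 measured members of the immediate early and heat shock list were lower, with a median log2 fold change of -1.19 (camera adjusted p = 7.16e-20). The adjusted p was 0.139 with an estimated correlation. Adjusted over the list alone, 8 members fell (Fosb, Egr1, Fos, Junb, Jun, Zfp36, Dusp1 and Ier2), and over all genes 0 did. Fosb was at 254.7 ± 131 CPM in ATR WT and 47.7 ± 8.06 CPM in ATR mD/mD (SD, n = 3), a log2 fold change of -2.42 (SE 0.398, adjusted p = 0.501, edgeR). Fos was at 748 ± 355 and 149.6 ± 42.3 CPM (log2 fold change -2.32, SE 0.422), and Egr1 at 730.2 ± 231 and 269.6 ± 17.3 CPM (-1.44, SE 0.25). Junb was at 384 ± 122 and 146.5 ± 21 CPM (-1.39, SE 0.271). In each of these 4 genes, every ATR WT library was above every ATR mD/mD library. DESeq2 called all 4 and the exact test called Fosb and Fos over all genes. The list passed with any 1 library left out, the highest adjusted p being 2.14e-09 (camera).

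**Figure D3:**
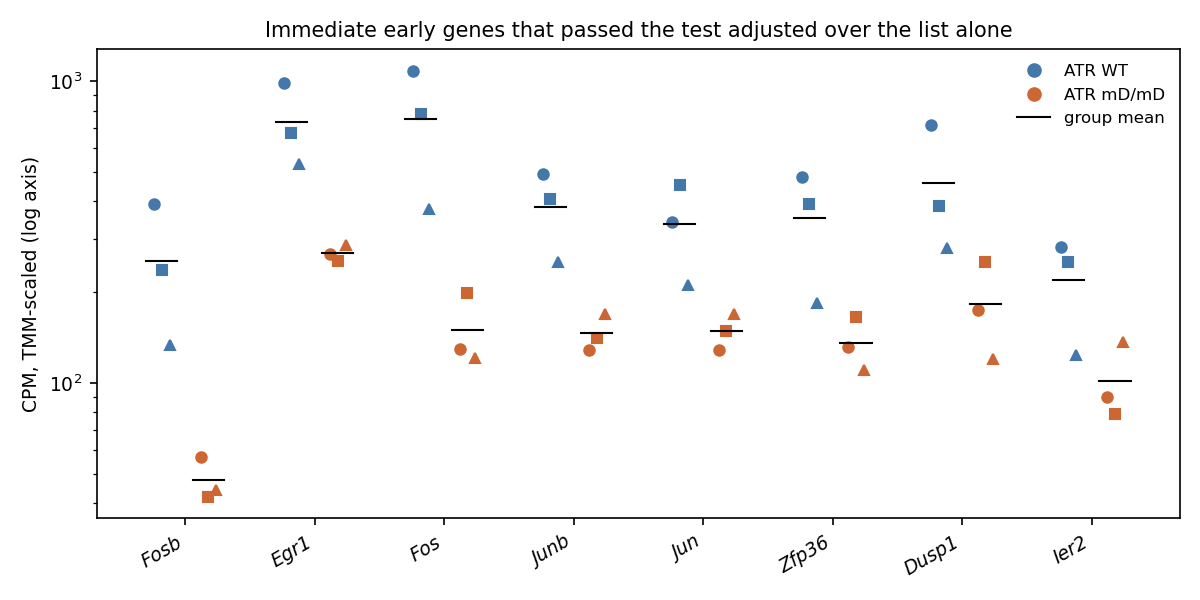
TMM-scaled CPM on a log axis of the 8 immediate early genes that fell when adjusted over the list alone, 1 point per library (circle, square and triangle for replicates 1, 2 and 3), with ATR WT in blue, ATR mD/mD in orange and a line at each group mean. Fosb ran from 134 to 394 CPM in ATR WT and from 41.9 to 56.9 CPM in ATR mD/mD.

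Transcriptional targets of MAPK signalling were lower as well. All 17 measured members of the list had negative log2 fold changes, with a median of -0.30 (camera adjusted p = 4.94e-08), although the adjusted p was 0.274 with an estimated correlation. No member passed over all genes or adjusted over the list alone. The feedback inhibitors Spry4 and Dusp6 were at 21.9 ± 4.63 and 130.3 ± 10.3 CPM in ATR WT and at 12.5 ± 1.81 and 74.1 ± 24.5 CPM in ATR mD/mD (SD, n = 3), log2 fold changes of -0.81 (SE 0.207) and -0.82 (SE 0.24). Ier3 and Phlda1 had log2 fold changes of -0.72 (SE 0.194) and -0.55 (SE 0.234).

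Several immune groups were lower as sets, none with a member that passed over all genes or adjusted over the list alone. Of 26 chemokine genes, 18 were lower, with a median of -0.31 (camera adjusted p = 9.18e-06, and adjusted p = 0.438 with an estimated correlation). Cxcl9 and Cxcl10, interferon-induced attractants of T cells, were at 14.03 ± 0.875 and 9.53 ± 0.305 CPM in ATR WT and at 6.06 ± 2.26 and 3.72 ± 1.62 CPM in ATR mD/mD (SD, n = 3). Their log2 fold changes were -1.21 (SE 0.305) and -1.36 (SE 0.371), and those of Cxcl1 and Xcl1 were -1.52 (SE 0.357) and -1.28 (SE 0.353). Of 18 T and NK cell markers, 12 were lower, with a median of -0.16 (camera adjusted p = 0.00239, and adjusted p = 0.671 with an estimated correlation). Cd4 was at 8.62 ± 2.27 and 4.11 ± 0.168 CPM (log2 fold change -1.07, SE 0.254), and Zap70, a kinase of the T cell receptor pathway, had -0.56 (SE 0.274). The T cell markers Cd3d, Cd3e, Cd3g and Cd247 stayed near 0, with 0.02 (SE 0.359), -0.06 (SE 0.44), 0.08 (SE 0.291) and -0.02 (SE 0.3325). Of 31 interferon response genes, 20 were lower (median -0.15, camera adjusted p = 0.00357, and adjusted p = 0.671 with an estimated correlation), among them Gbp3 with -0.44 (SE 0.173) and Irgm1 with -0.37 (SE 0.16). Of 13 cytokine genes, 9 were lower (median -0.20, camera adjusted p = 0.00674, and adjusted p = 0.438 with an estimated correlation), such as Il1b with -0.89 (SE 0.421). Tnf had -1.04 (SE 0.612), which rested on ATR WT 2 alone and was 0.030 without it. The T and NK cell call was lost without ATR WT 1, ATR mD/mD 2 or ATR mD/mD 3 (adjusted p 0.0993, 0.102 and 0.971, camera). On mean log2 CPM, the T and NK cell median was -0.21 with all libraries, 0.0033 without ATR mD/mD 3 and -0.47 without ATR mD/mD 1. The interferon call was lost without ATR WT 1 or ATR mD/mD 2 (0.335 and 0.944), and the cytokine call without ATR WT 1 or ATR mD/mD 3 (0.203 and 0.691), whereas the chemokine call was kept each time. The size of the chemokine difference still moved: on mean log2 CPM its median was -0.35 with all libraries, -0.16 without ATR mD/mD 2, -0.21 without ATR WT 3 and -0.59 without ATR mD/mD 3.

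Pigment cell and hair lists were lower as sets under the preset correlation, while the hair level itself divided the libraries in a way that did not follow genotype. Of 18 melanocyte and pigment genes, 16 were lower in ATR mD/mD, with a median of -0.52 (camera adjusted p = 0.000174, and adjusted p = 0.671 with an estimated correlation). Sox10, a transcription factor of melanocytes and Schwann cells, was at 36.7 ± 6.40 CPM in ATR WT and 20.7 ± 2.98 CPM in ATR mD/mD (SD, n = 3), a log2 fold change of -0.83 (SE 0.183). Tyr, the enzyme that starts melanin synthesis, was at 27.2 ± 19.99 and 13.6 ± 18.8 CPM (-1.003, SE 1.15), and Gpnmb and Mitf had -0.77 (SE 0.516) and -0.29 (SE 0.242). Of 34 hair follicle genes, 33 were lower, with a median of -0.67 (camera adjusted p = 3.14e-07, and adjusted p = 0.671 with an estimated correlation of 0.86). The hair keratins Krt82 and Krt83 and the hair desmoglein Dsg4 had log2 fold changes of -1.62 (SE 1.63), -1.86 (SE 2.09) and -2.32 (SE 1.92), and Gata3 had 0.20 (SE 0.228). In none of the 34 hair genes did the groups separate, and the lowest unadjusted p was 0.269 (edgeR). The melanocyte call was lost without ATR mD/mD 2 (adjusted p = 0.0789) and the hair call without ATR mD/mD 1 (0.133, camera). Single libraries also moved the size of both differences. On mean log2 CPM, the hair median was -2.62 with all libraries, -0.73 without ATR mD/mD 1 and -5.14 without ATR mD/mD 3. The melanocyte median was -0.91 with all libraries, -0.31 without ATR WT 2 and -2.02 without ATR mD/mD 3. With the hair list level as a covariate, chosen after the data were examined, the adjusted p of the melanocyte list was 0.945 (camera). Of 16 Schwann and nerve markers, 15 were lower (median -0.17, camera adjusted p = 0.000174, and adjusted p = 0.438 with an estimated correlation), among them Sox10 again and the glial calcium-binding protein gene S100b (-0.52, SE 0.318). That call was lost without ATR WT 1 or ATR mD/mD 3 (adjusted p 0.0662 and 0.232, camera). On mean log2 CPM, the Schwann and nerve median was -0.21 with all libraries. It was -0.063 without ATR WT 1, 0.030 without ATR mD/mD 3 and -0.40 without ATR mD/mD 2.

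Connective tissue, senescence and p53 lists were also lower. Of 22 fibroblast and matrix genes, 21 were lower, with a median of -0.32 (camera adjusted p = 4.34e-07, and adjusted p = 0.391 with an estimated correlation). The collagen VI genes Col6a1, Col6a2 and Col6a3 had log2 fold changes of -0.35 (SE 0.19), -0.37 (SE 0.169) and -0.59 (SE 0.262). Of 20 senescence and secretory phenotype genes, 14 were lower (median -0.22, camera adjusted p = 0.000174, and adjusted p = 0.274 with an estimated correlation). Adjusted over the list alone, 2 members fell, and over all genes 0 did. These were Cxcl1, also on the chemokine list, and Glb1, the lysosomal beta-galactosidase, with 25.1 ± 2.19 and 16.4 ± 0.839 CPM (SD, n = 3; log2 fold change -0.61, SE 0.133). Glb1 lies 18.5 Mb from Atr on chromosome 9. Of 27 p53 target genes, 16 were lower, with a median of -0.04 (camera adjusted p = 0.045, and adjusted p = 0.391 with an estimated correlation). Btg2 and Gdf15 had log2 fold changes of -0.86 (SE 0.291) and -1.02 (SE 0.367), and the call was lost without ATR WT 1, ATR mD/mD 2 or ATR mD/mD 3 (adjusted p 0.307, 0.1003 and 0.323, camera). The p53 call was also lost with the replicate number as a block (adjusted p = 0.0896, camera).

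**Figure D4:**
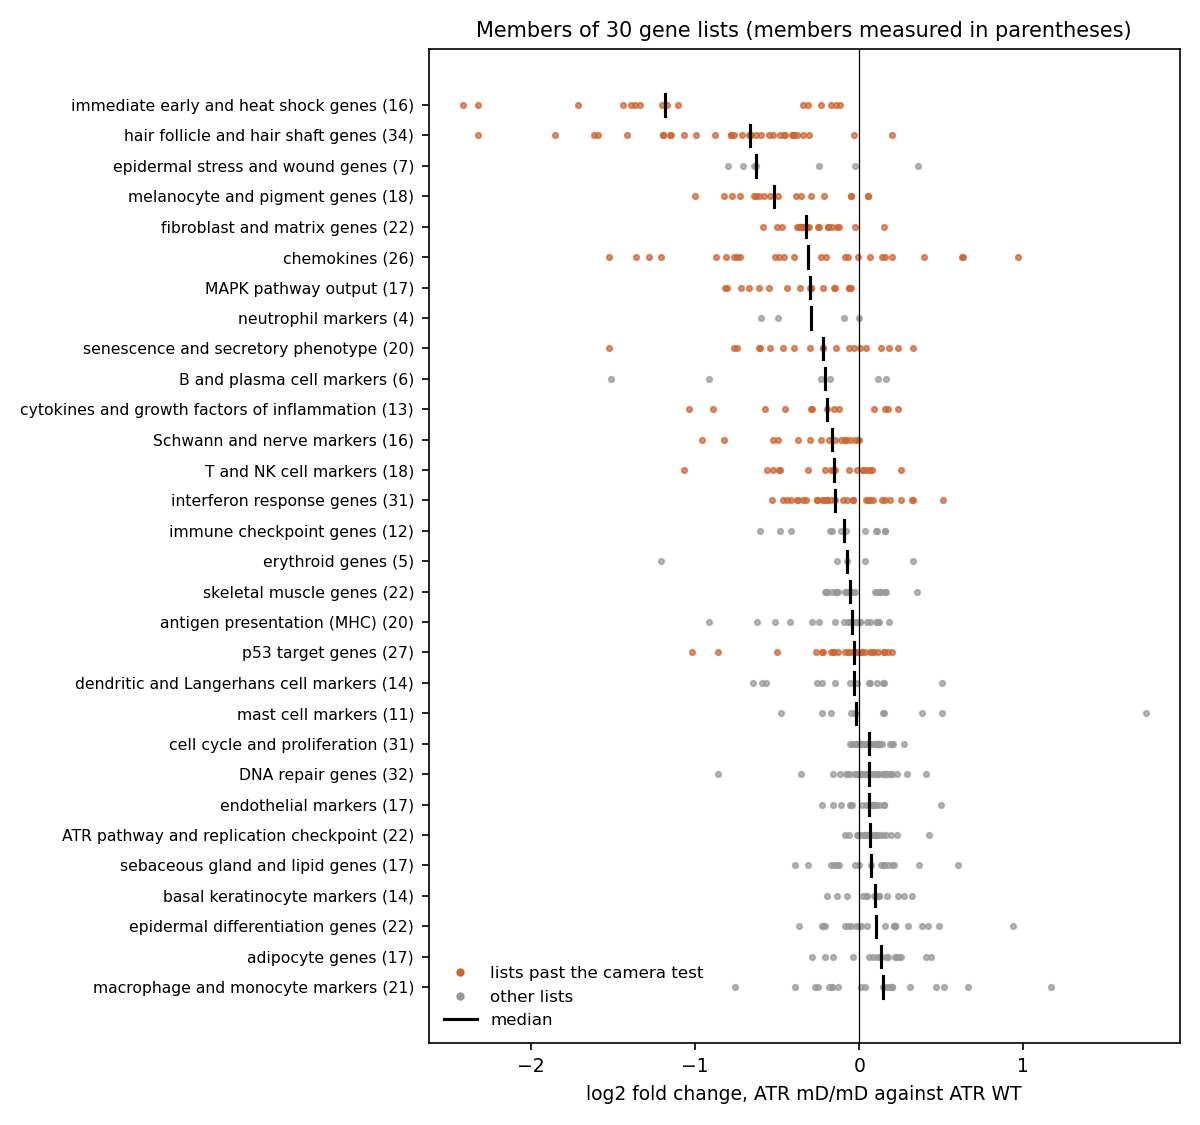
Log2 fold changes of the members of 30 gene lists, 1 point per gene, with a line at each list's median, and lists past the camera test in orange. Immediate early and heat shock genes had a median of -1.19 and macrophage markers one of 0.14, and the sex-linked list was left out because its members follow the sex of the libraries.

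The other 19 measured lists did not pass the camera test, and none of their members passed over all genes or adjusted over the list alone. Of 22 genes of the ATR pathway and replication checkpoint, 17 were higher, with a median of 0.06 (adjusted p = 0.175), and Smarcal1 and Wee1 had log2 fold changes of 0.16 (SE 0.137) and 0.23 (SE 0.211). With the hair list level as a covariate, this list was higher at an adjusted p of 0.0063 (camera), and adjusted p = 0.343 with an estimated correlation. DNA repair genes had a median of 0.06 (adjusted p = 0.256), with the damage sensor gene Xpc at 0.23 (SE 0.117). Basal keratinocyte markers had a median of 0.09 (adjusted p = 0.1505), with Col17a1 at 0.27 (SE 0.234), and epidermal differentiation genes had 0.10 (adjusted p = 0.171), with Klk5 at 0.94 (SE 0.356). Macrophage and monocyte markers had a median of 0.14 (adjusted p = 0.837), with C1qb at -0.39 (SE 0.211) and Retnla at 1.17 (SE 0.682). Immune checkpoint genes had -0.09 (adjusted p = 0.175), with Lag3 at -0.48 (SE 0.289), antigen presentation genes -0.04 (adjusted p = 0.125), and dendritic and Langerhans cell markers -0.03 (adjusted p = 0.1097). The medians of B and plasma cell, neutrophil and erythroid genes were -0.21, -0.29 and -0.07 (adjusted p 0.463, 0.489 and 0.661). Epidermal stress and wound genes had -0.63 (adjusted p = 0.182), and sex-linked genes had 1.30 (adjusted p = 0.1795). Adipocyte, endothelial and sebaceous genes had medians of 0.13, 0.06 and 0.07 (adjusted p 0.263, 0.569 and 0.599).

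Single libraries decided many of these results at the preset correlation of 0.01, ATR mD/mD 1 most often. With all libraries, none of these lists passed with an estimated correlation (adjusted p 0.671 or above). Without ATR mD/mD 1, camera at the preset correlation gave lower antigen presentation, dendritic cell, checkpoint and macrophage genes (adjusted p 7.09e-08, 2.15e-06, 0.00151 and 0.00599). It gave higher ATR pathway, DNA repair and sex-linked genes (0.00461, 0.0305 and 0.00276) in the same setting. Antigen presentation genes were also lower without ATR WT 2 or ATR WT 3 (0.00644 and 0.0181, camera). Without ATR WT 1, epidermal differentiation genes were higher (0.000145) and epidermal stress genes lower (0.00671), the latter also without ATR mD/mD 3 (0.00195, camera). Basal keratinocyte markers were higher without ATR WT 3 (0.0368), and adipocyte genes were higher without ATR mD/mD 3 (3.63e-05, camera).

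In 3 lists the test and the median differed in sign. Cell cycle and proliferation genes had a median of 0.06 and a mean of 0.07, 27 of 31 members being higher, while camera gave the direction as lower (adjusted p = 0.661). Skeletal muscle genes had a median of -0.06 and a mean of -0.02, while camera gave higher (adjusted p = 0.639). Mast cell markers had a median of -0.02 and a mean of 0.18, and camera gave higher (adjusted p = 0.463). Among them Tpsab1 was at 1.03 ± 0.211 CPM in ATR WT and 3.45 ± 1.71 CPM in ATR mD/mD (SD, n = 3), a log2 fold change of 1.74 (SE 0.416, adjusted p = 0.9999, edgeR). Cell cycle genes moved with single libraries: camera gave lower without ATR mD/mD 3 (adjusted p = 2.03e-10) and higher without ATR mD/mD 1 (0.0333) or ATR mD/mD 2 (0.0472). Muscle genes were higher without ATR WT 1 (7.48e-05) or ATR mD/mD 3 (0.000849) and lower without ATR WT 3 (0.0135), and mast cell genes were higher without ATR mD/mD 3 (0.00143, camera). These calls rest on the preset correlation of 0.01. With all libraries the estimated correlations were 0.862, 0.96 and 0.776 for cell cycle, muscle and mast cell genes, and adjusted p = 0.941, 0.941 and 0.847 with an estimated correlation. None of the 12 lists past the test passed with an estimated correlation or with fry, and 5 of the 12 passed with any 1 library left out, namely the immediate early, MAPK, fibroblast, chemokine and senescence lists. The size of these differences was less steady than the calls. With 1 library left out, list medians on mean log2 CPM ran from -0.12 (without ATR mD/mD 2) to -0.59 (without ATR mD/mD 3) for senescence genes, against -0.24 with all libraries. They ran from -0.23 (without ATR mD/mD 1) to -0.49 (without ATR mD/mD 3) for MAPK targets, against -0.35, and from -0.19 (without ATR mD/mD 1) to -0.38 (without ATR mD/mD 2) for fibroblast genes, against -0.32. For immediate early genes they ran from -0.82 (without ATR WT 1) to -1.43 (without ATR WT 3), against -1.09.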

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

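Covariates for hair level and Y-linked level (also with an estimated correlation), the exact test, robust estimation, the 10 CPM minimum, keeping rows without a gene and leaving out keratin loci were chosen after the data were seen. The planned filters at 1 CPM and with no filter removed no gene and are no test of stability. RLE size factors, limma-voom, robust estimation, a 2-fold minimum and kept rows each gave the same 7 genes, RLE moving the median log2 fold change by 0.00114. DESeq2 gave 39 genes (33 lower, 6 higher) and the exact test 22 (20 lower, 2 higher), each including all 7. An adjusted p under 0.01 left 5, and a 10 CPM minimum left 5, since Trim12a and Rnaset2b were not tested. The Y-linked covariate left 4 genes, all lower (Rnaset2b, Trim12a and Zfp949 lost their calls, although their log2 fold changes were -5.68, -9.54 and -1.65 against -5.72, -9.55 and -1.69), and the hair covariate gave 10, of which 1 (Cfap74) was higher. With 1 library left out, the calls ran from 4 to 10, lower genes from 4 to 9 and higher genes from 0 to 1 (Cfap74 without ATR mD/mD 3, Gm1821 without ATR WT 1). The labels do not say whether replicate numbers pair the samples. Deviations of same-numbered libraries correlated at 0.633, -0.509 and 0.573, and ATR WT 2 correlated best with ATR mD/mD 3. The first principal component correlated at 0.989 with hair level, so these values may follow hair and cannot decide whether same-numbered samples were paired. The replicate block gave 6 genes, without Rnaset2b and Zfp949 and with Alpi, and 12 lists, 11 of them shared. With the block, p53 target genes lost the call (adjusted p = 0.0896) and epidermal stress genes gained it as lower (adjusted p = 0.00586, camera). Of the 12 lists, 0 passed with an estimated correlation, with or without a covariate, and 0 with fry. Leaving out 1 library gave 9 lists (ATR mD/mD 2) to 19 (ATR mD/mD 1). Among values of single genes, lists and loci, 1634 kept direction and side of the threshold, 83 lost the call, 53 gained one and 74 turned. The 1634 overstate stability, since they include the filter settings that removed no gene and many genes far from the threshold. Atr ran from -0.095 to 0.11 with 1 library left out, Braf from -0.38 to 0.060, Tnf from -1.40 to 0.030, Skint1 from -0.036 to 0.21 and Skint2 from -0.097 to 0.13. With the hair covariate Braf was 0.16 and Skint2 -0.050. Medians of list differences in mean log2 CPM follow for lists whose test direction turned. With 1 library left out, immune medians ran from -0.20 to 0.27 for macrophage, -0.17 to 0.26 for mast cell, -0.26 to 0.091 for antigen presentation, -0.39 to 0.020 for B cell, -0.53 to 0.17 for neutrophil, -0.24 to -0.031 for interferon and -0.33 to 0.083 for dendritic cell genes. They ran from -0.64 to 0.18 for cell cycle, -0.055 to 0.11 for ATR pathway, -0.065 to 0.13 for DNA repair and -0.13 to 0.043 for erythroid genes. Skin and tissue medians ran from -0.016 to 0.46 for epidermal differentiation, -2.24 to 0.015 for epidermal stress, -0.11 to 0.15 for sebaceous, -0.43 to 0.63 for muscle, -0.092 to 0.40 for adipocyte and -0.12 to 0.14 for endothelial genes. With the hair covariate, under either correlation, they were -0.011 for melanocyte, 0.037 for macrophage, 0.034 for neutrophil, -0.14 for mast cell, 0.33 for cell cycle and 0.42 for epidermal stress genes. The hair median was -0.032, a value fixed near 0 in advance because the covariate was the mean of that same list. Medians were -0.045 for sebaceous, -0.13 for adipocyte, -0.53 for muscle and -0.043 for endothelial genes. With the Y-linked covariate, under either correlation, they were -0.051 for B cell, -0.016 for neutrophil, 0.097 for dendritic cell, 0.016 for checkpoint, -0.13 for muscle and -0.029 for endothelial genes. With a 10 CPM minimum they were -0.069 for mast cell and 0.018 for erythroid genes. The cause of these changes was not tested, except that leaving out a library leaves fewer samples. Depth limits genes with few counts: at 1, 0 and 0 reads in ATR mD/mD, the Skint4 ratio is bounded only between 327 and 72070.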

Other observations

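The tests of the linked segment around Atr and of basal keratinocytes were written after the results were seen, and the covariates for hair level and Y-linked level, their repeats with an estimated correlation and the count without keratin loci are unplanned alternatives. SEs of list medians in this section come from resampling the member genes, so they leave out the spread between libraries. Some transcripts jumped between libraries without following genotype. The Gt(ROSA)26Sor transcript, from a locus often used for knock-in alleles (chromosome 6, 113067428 to 113077333), had 453, 631 and 605 counts in ATR WT and 440, 16 and 26 in ATR mD/mD. H2-Eb1, an MHC class II gene, had 367 counts in ATR mD/mD 2 and between 6914 and 22410 in the other libraries, while its neighbour H2-Ea-ps had 0 counts in ATR WT 3 and between 86 and 351 elsewhere. Zfp429 had 3 counts in each of ATR mD/mD 1 and ATR mD/mD 2 and 62 to 132 elsewhere. AI506816 had 5 counts in ATR mD/mD 1 and 342 to 1590 elsewhere. Mrgprg, a receptor of the Mas-related family, had 1460 counts in ATR mD/mD 2 and 12 to 104 elsewhere. In the higher direction, Cfap74, a cilia-associated gene, was at 2.16 ± 0.245 CPM in ATR WT and 14.4 ± 4.21 CPM in ATR mD/mD (SD, n = 3), a log2 fold change of 2.73 (SE 0.288, adjusted p = 0.0758, edgeR). With 1 library left out, its adjusted p ran from 0.0289 (without ATR mD/mD 3, the only passing value) to 0.505 (without ATR WT 2).

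With the hair list level as a covariate, 6 further lists passed the camera test at the preset correlation. Cell cycle genes were higher (median 0.33 on mean log2 CPM, adjusted p = 2.48e-06), skeletal muscle genes lower (-0.53, adjusted p = 4.61e-10) and antigen presentation genes lower (-0.27, adjusted p = 8.26e-05). ATR pathway and DNA repair genes were higher (0.12 and 0.15, adjusted p 0.0063 and 0.0122), and dendritic and Langerhans cell markers lower (-0.20, adjusted p = 0.0122). With an estimated correlation none of the 6 passed: the adjusted p was 0.688 for cell cycle, 0.540 for muscle and antigen presentation, 0.343 for ATR pathway, 0.301 for DNA repair and 0.725 for dendritic cell genes. The estimated correlations were 0.766 for muscle and 0.681 for cell cycle genes. T and NK cell markers had a median of -0.38 in the covariate fit (adjusted p = 4.27e-08, and adjusted p = 0.301 with an estimated correlation). With the Y-linked level as a covariate, the adjusted p of T and NK cell markers was 0.112, while macrophage and mast cell markers were higher (0.27 and 0.11, adjusted p 0.000285 and 0.0081, and adjusted p 0.334 and 0.867 with an estimated correlation). Across the alternatives, the adjusted p of T and NK cell markers ran up to 0.971 (camera). The covariate fits leave 3 residual degrees of freedom, and hair level was itself uneven between the groups.

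The 10 possible splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The genotype split gave 7 genes and the highest of the other splits 1966, and 2 of the 10 splits gave at least as many genes. For each direction, the larger direction of every other split was taken, since neither of its sides stands for ATR mD/mD. For lower genes the real count was 7 and the highest other 1050 (916 in the opposite direction of that split), reached or passed in 2 splits. For higher genes it was 0 against 1050, which all 10 splits reached. For gene lists it was 12 against 20, reached in 4 splits. All these numbers of splits include the genotype split itself. The split with 1966 genes put ATR WT 1, ATR mD/mD 1 and ATR mD/mD 2 against the rest. That is the division by hair gene level, which points to a structure of the samples. The split by sex-linked transcripts gave 6 genes.

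The near-absent transcripts in ATR mD/mD may be strain variants, since the labels give a mixed C57BL/6-129J background, and a biological effect of Atr stays open beside that. Fewer basal keratinocytes are argued against, since the basal keratinocyte median was 0.0946 (SE 0.0381 over resampled member genes), far from the loss that near-absent epidermal transcripts would need. With 1 library left out, that median on mean log2 CPM ran from 0.016 (without ATR WT 2) to 0.13 (without ATR WT 3). Of 20 autosomal loci with a jump of over 8-fold between libraries, those with the exact hair division left out, 4 followed genotype (20%, exact 95% interval 5.73 to 43.7) and 11 were set by a single library, and without 3 remaining keratin loci it was 4 of 17 (23.5%, 6.81 to 49.9). A locus set by a single library cannot follow a split of 3 against 3, so counting these 11 lowers the share. The loci that followed genotype hold the near-absent genes themselves. The share therefore cannot decide whether such variants segregated within the cross. Of the 9 loci with at least 2 libraries on each side, however, 4 followed genotype and the other 5 (4 without a keratin locus) each followed a different split, and no p-value was computed for that share. Near Atr, 12 of 273 genes within 20 Mb had p under 0.01 against 62 of 13652 other autosomal genes (odds ratio 10.1, 95% interval 4.88 to 19.2, Fisher's exact one-sided p = 1.89e-08, and p = 0.0011 by rotating gene order; 5.07, 2.43 to 9.58, with the hair covariate, and 5.23 at p under 0.05), among them Zfp949, Pxylp1 (log2 fold change -1.43) and Col6a5 (1.55), as a linked segment carried with the targeted allele would give. The near-absent transcripts lie on chromosomes 1, 4, 7 and 17, so a segment linked to Atr on chromosome 9 would not account for them. The share of genes with p under 0.01 was 1.7% on chromosome 9. It was also 1.24% on chromosome 7, 1.28% on chromosome 17 and 1.11% on chromosome 4, against at most 0.637% on any other autosome. Chromosome 1, which also holds near-absent transcripts, had only 0.355%. These shares count the near-absent genes and their neighbours themselves.

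The lower immediate early genes were set against uneven hair growth and uneven sex. With the hair level as a covariate the list median was -1.241 (SE 0.372) and with the Y-linked level -1.236 (SE 0.347), against -1.185 without either, and all 16 members stayed lower in both fits. Both values argue against these as the whole cause, although their SEs come from the member genes and not from the spread between libraries. Immediate early transcripts also respond to handling and to the time between death and freezing, which the labels do not give, so this explanation is untested. An effect of Atr genotype is a hypothesis that may account for the pattern and stays open with it.

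The lower melanocyte genes were set against the same 2 explanations. With the hair level as a covariate, the list median moved from -0.518 to -0.015 (-0.01509, SE 0.0702), and 9 of 18 members were lower, although Sox10 kept most of its difference (log2 fold change -0.83 without and -0.70 with the covariate, SE 0.15, unadjusted p = 0.0026, adjusted p = 0.707, edgeR). With the Y-linked level it was -0.5277 (SE 0.164, again without the spread between libraries), which argues against uneven sex as the whole cause. Uneven hair growth may therefore account for the lower list median, since growing follicles hold pigment cells, and the Sox10 difference stays open. A smaller number of melanocytes in ATR mD/mD nevi was not tested apart from hair level.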
